A study of Salvelinus fontinalis with 118 samples.

How the data were processed

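Gill filaments of brook trout (Salvelinus fontinalis, a cold-water salmonid) were sampled in 4 streams of central Pennsylvania in July and August, over 2 successive heatwaves and 4 phases of each: increasing temperature, peak, post-peak and recovery. Each combination of stream, heatwave and phase was 1 sampling event with 1 date and 1 water temperature, which gave 32 events with 69 female and 49 male fish per the labels. Of the events 1 held 2 fish, 8 held 3 fish and 23 held 4 fish.

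RNA was extracted with a NucleoSpin kit and made into TagSeq libraries, which sequence 1 tag near the 3′ end of each transcript, per the labels' protocols. The files hold expected counts of reads per contig as deposited by the authors, which Salmon 1.10.0 estimated per the submitters' processing notes. They also hold TPM (transcripts per M, scaled by contig length) as deposited by the authors from the same Salmon run, which were not used, since tags from transcript ends do not scale with length. The index, its annotation and any read filter are not given in the sources used here. Every file lists the same 69441 contigs, of which 9119 have no name. Expected counts of contigs with the same name were summed and rounded to whole numbers, which left 34828 features: the 9119 unnamed contigs, 11981 features named by a LOC identifier and 13728 with another name. Of the names, 16437 stood on 1 contig and 1294 on more than 5, up to 924 contigs for 1 name. A sum of that kind can merge paralogs or members of a gene family, and the salmonid genome duplication left many close copies, so values of such names are uncertain as to the copy. A RefSeq gene table of assembly ASM2944872v1 matched 2164 of the names and 0 of the LOC identifiers. It was used for no coordinates, and the build behind the contigs is not given in the sources used here. No product names could be joined to the features, so genes are named as in the files, and the part of the fixed rules that relied on product names was applied to symbols only.

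The libraries held a median of 8.74 M reads (1.06 to 14.7 M, the second lowest 5.06 M) on a median of 44192 contigs with at least 1 read. Unnamed contigs took a median of 7.1% and LOC-named features 31.0% of the reads. Features named for 45S ribosomal RNA took a median of 2.77% (0.57% to 8.42%) and stayed in the library sizes, with an alternative without them. Library sizes set the precision of each value, and no molecular identifiers were used here, so counting error is only part of the spread. No 2 libraries were identical: the highest correlation of log2 CPM (counts per M reads of a library) between libraries was 0.959. It lay between fish 21 of the Standing Stone heatwave 1 peak and fish 54 of its heatwave 2 post-peak. Whether fish were related or sampled again was not tested.

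Because water temperature, phase and stream are shared by all fish of an event, the reads of its fish were summed and the event was the replicate (15.4 to 41.5 M reads each). For sex, the fish was the replicate. Genes were kept by edgeR's filterByExpr with a minimum count of 10 and the streams as groups, which removed 8892 and left 24686 genes. Counts were scaled with TMM (factors 0.88 to 1.15) and tested with edgeR's quasi-likelihood test (version 4.0.16 in R 4.3.3), with Benjamini-Hochberg (BH) adjustment and a threshold of 0.05. The biological coefficient of variation was 0.211 in the temperature fit. Temperature was fitted as a slope within streams (log2 per °C), with stream as a covariate. The phase contrasts had stream and heatwave as covariates, the heatwave contrast had stream and phase, and the stream tests had heatwave and phase. Interactions were tested as such: 1 slope per stream, and phase by heatwave. Sex was tested with the event as a covariate. Standard errors (SE) were derived as the absolute log2 fold change or slope divided by the square root of the quasi-likelihood F statistic. CPM values are means ± SD over events.

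The groups, tests, covariates, alternatives, gene lists and the rule for named genes were fixed before the data were examined. The rule took, per comparison, up to 8 genes with the highest and 8 with the lowest fold change or slope among those past the threshold, with a mean log2 CPM of at least 2, an informative symbol and the same direction in all 4 streams. For warm against cool streams, it asked that both warm streams lie on one side of both cool streams. It added the 3 members of each gene list with the smallest p, and a panel reported in every comparison: the most abundant feature named for cold-inducible RNA-binding protein (CIRBP), serpin H1 (HSP47), HSP 90-alpha (HS90A), the 70 kDa heat shock protein (HSP70) and its cognate (HSPA8). Genes outside the rule are named as such where they appear, except HSP90BB for temperature and HSPB7, CALRL and COL28A1 for warm against cool streams, which complete small counts and were named after their values were seen. Some genes that the rule took are not reported here.

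The 29 gene lists were tested with camera and fry of limma 3.58.1 for temperature, peak against recovery, heatwave and warm against cool streams, BH-adjusted over the lists of a comparison. Members were counted as past the threshold over all genes and adjusted over the list alone. Symbol patterns took in some other genes (TAP26 as antigen presentation, MXRA8 as interferon response, LOX5 as collagen and matrix, CD226 as B cell marker, MYH10 as muscle). They left out genes with UniProt-style names, such as HS90A. Keratins had 0 members and cold-inducible RNA-binding proteins 1, so these 2 lists had no set test. HSP90B1 was in the heat shock and the endoplasmic reticulum lists, and PSMB8B and PSMB9-B in the proteasome and antigen presentation lists. Gill expresses genes of all these lists, including those that mark blood and immune cells.

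The tests were run on simulated data made from the real means and library sizes, with 100 genes changed at each of 2 sizes per comparison. Counts were drawn independently around the overall mean of each gene, without stream differences, shared days or correlation between genes. The changed genes were not drawn from the least abundant ones. The shares that follow hold for that model and do not give the power or error rate of the real data. Of simulated temperature slopes, 79% were recovered at 0.2 log2 per °C and 96% at 0.5, and 3.8% of calls were false. For peak against recovery 52% were recovered at a log2 change of 0.5 and 93% at 1, with 4.6% false calls. The shares were 73% and 93% for heatwave (2.9% false calls), 77% and 97% for warm against cool streams (3.9%) and 75% and 91% for sex (2.4%).

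Alternatives were RLE factors, DESeq2 1.42.0, no filter, contigs one by one, each fish as the replicate in edgeR or in limma with a correlation within events, mean log2 CPM per event, further covariates, and each event, stream or fish place left out. Chosen after the data were seen were fits without the 3 libraries with the fewest contigs, without 45S features, within each heatwave, without the recovery events of heatwave 2, with a block that pairs events by stream and heatwave or by stream and phase, and gene lists extended to the naming of the files. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 was used for tables and plots.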

Results

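Gill expression was measured by 3′ tag sequencing in wild brook trout over 2 summer heatwaves, with 31 fish from Big Poe, 27 from East Branch Standing Stone, 30 from Shavers Creek and 30 from Standing Stone. Increasing, peak, post-peak and recovery phases held 28, 31, 30 and 29 fish, and heatwaves 1 and 2 held 57 and 61. Water at sampling was warmer in Big Poe (17.7 ± 1.8 °C, SD over 8 events) and Shavers (18.2 ± 1.33 °C) than in East Branch (14.2 ± 0.91 °C) and Standing Stone (14.8 ± 1.01 °C). These are called the warm and the cool streams. The mean was 16.7 °C in the increasing phase, 17.5 °C at the peak, 15.8 °C post-peak and 14.9 °C in recovery, and recovery was cooler in heatwave 2 (13.9 °C) than in heatwave 1 (15.8 °C). Phases are as labelled and did not follow temperature in every stream. In heatwave 1 the East Branch peak (14.4 °C) was cooler than its increasing event (15.2 °C). The Big Poe recovery of heatwave 1 (17.5 °C) was warmer than its post-peak (16.6 °C). Libraries held a median of 8.74 M reads (1.06 to 14.7 M).

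Summed per event, gill transcriptomes separated by stream more than by phase or heatwave. The first principal component of the 32 events held 11.0% of the variance, and stream accounted for 86.1% of its spread, phase for 0.4% and heatwave for 1.1%. Stream accounted for 26.3% of the second component (8% of the variance; phase 2.8%, heatwave 7.4%), 78.5% of the third (6.5%) and 83.0% of the fourth (5.9%). Among single fish the first component (12% of the variance) had 1.2% of its spread by stream, 3.4% by phase and 0.2% by heatwave, and the 3 libraries with few contigs described next had its highest scores (472.0, 170.6 and 114.1, the next 51.0). Stream accounted for 13.2%, 36.7% and 37.8% of the next 3 components of single fish in turn.

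**Figure D1:**
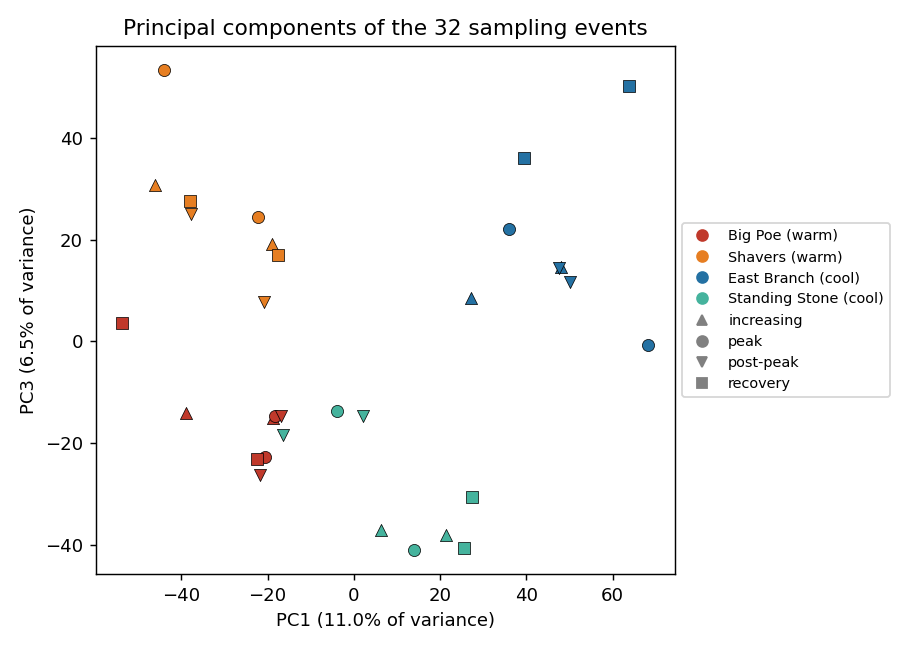
Principal components 1 (11% of variance) and 3 (6.5%) of log2 CPM of the 32 sampling events, 1 point per event, coloured by stream and shaped by phase. Stream accounted for 86.1% of the spread on component 1 and 78.5% on component 3.

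Among single fish, 3 libraries stood apart with few contigs detected: fish 44 of the East Branch heatwave 2 recovery (13621 contigs, 1.06 M reads), fish 61 of the Shavers heatwave 2 peak (29147) and fish 75 of the Big Poe heatwave 2 recovery (31018 contigs, 14.7 M reads). The other libraries had 37569 contigs or more.

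**Figure D2:**
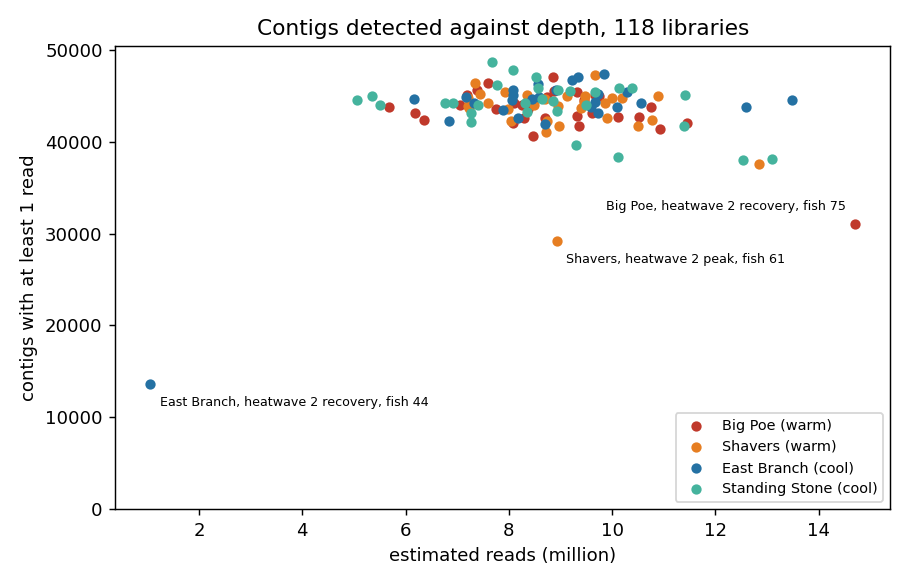
Contigs with at least 1 read against reads in M for every library, 1 point per fish, coloured by stream. The 3 libraries named beside their points had 13621, 29147 and 31018 contigs, the others at least 37569.

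Some chaperone genes rose with water temperature within streams. HSP47, the collagen chaperone of the endoplasmic reticulum, rose by 0.51 ± 0.07 log2 per °C (SE, 32 events; edgeR, BH-adjusted p = 0.000598) in 4 of 4 streams. HS90A, an inducible HSP90, rose by 0.40 ± 0.08 per °C (edgeR, BH-adjusted p = 0.0189), with a positive slope in 3 of 4 streams. FKBP5, a co-chaperone of steroid receptors induced by glucocorticoids, rose by 0.61 ± 0.13 per °C, and HSP70B by 0.24 ± 0.05 and HSP90BA, an abundant HSP90, by 0.14 ± 0.03 (edgeR, BH-adjusted p = 0.0224, 0.0319 and 0.0201). P4HA2, a collagen prolyl 4-hydroxylase subunit, rose by 0.18 ± 0.04 and CHAD, chondroadherin, by 0.26 ± 0.05 log2 per °C. BHMT, a methyltransferase of methionine synthesis, rose by 0.28 ± 0.06, PSS by 0.23 ± 0.05 and CCR9, a chemokine receptor, by 0.20 ± 0.04. All these had a positive slope in 4 of 4 streams except HS90A. The rule for the genes with the highest slopes asked for this, so for them it is no separate support.

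Among the genes that fell with temperature, HMGB3, a chromatin protein, did so by 0.13 ± 0.02 log2 per °C (edgeR, BH-adjusted p = 0.00391), SRSF2, a splicing factor, by 0.13 ± 0.03, TCPG, the gamma subunit of the CCT chaperonin, by 0.16 ± 0.03 and MERL, merlin, by 0.25 ± 0.05 (edgeR, BH-adjusted p = 0.0153, 0.0154 and 0.0153). KIF4, a mitotic kinesin, fell by 0.20, ANO8 and the forkhead factor FOXE1 by 0.18, and BRF2, a factor of RNA polymerase III, by 0.17 per °C. Their slopes were negative in 4 of 4 streams, which the rule that picked them required. CIRBP, the cold-inducible RNA-binding protein, had a slope of -0.16 ± 0.04 (edgeR, BH-adjusted p = 0.092), negative in 4 of 4 streams and short of the threshold. HSP70 (-0.03) and HSPA8 (0.04) did not pass. In all, 60 genes rose and 49 fell, 109 of 24686, and 3105 had an unadjusted p under 0.05 where chance gives 1234. The name HSP47 stood on 3 contigs, FKBP5 and HS90A on 1 each and CIRBP on 24, so the value of CIRBP may merge copies.

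**Figure D3:**
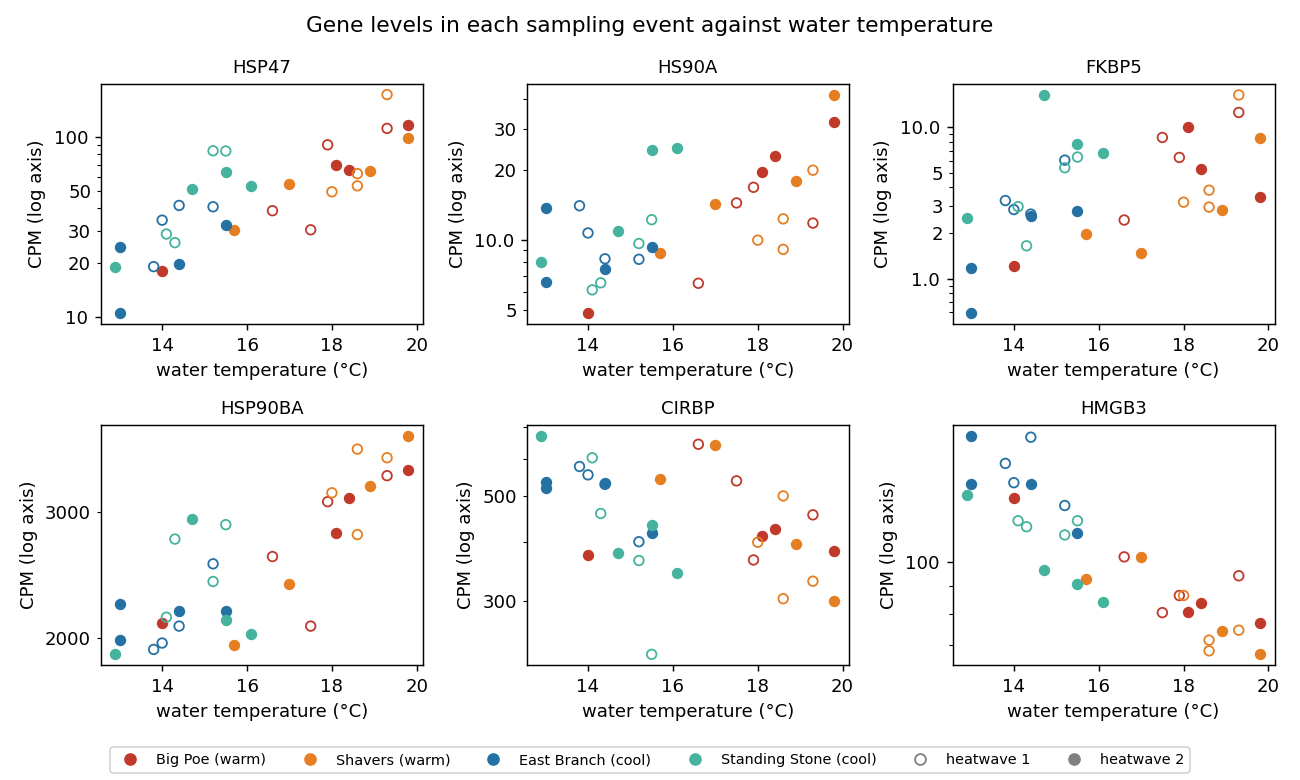
CPM (log axis) of HSP47, HS90A, FKBP5, HSP90BA, CIRBP and HMGB3 against water temperature in °C for the 32 sampling events, coloured by stream, open for heatwave 1 and filled for heatwave 2. HSP47 rose by 0.51 log2 per °C within streams, and HMGB3 fell by 0.13.

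The count of 109 changed with the events and fish in the fit. It was 3 without the Big Poe recovery event of heatwave 2, 51 without the Big Poe peak of heatwave 1, 71 without that of heatwave 2 and 174 without the Shavers peak of heatwave 2. With all 32 events kept, it was 34, 54, 4 and 183 without the fish in the 1st, 2nd, 3rd or 4th place of each event. Of the 3 libraries with few contigs, East Branch fish 44 was in the 1st place, Big Poe fish 75 in the 3rd and Shavers fish 61 in the 4th. The count was 42 without these 3 libraries, 0 without the 4 recovery events of heatwave 2, 342 by DESeq2 and 232 by limma with each fish as the replicate. Of the genes named, HSP47 still passed without the Big Poe recovery event at 0.53 log2 per °C, where CIRBP passed as well at -0.24 and the others did not. Without the 3 libraries FKBP5, HS90A, HSP70B, BHMT, CCR9, MERL, KIF4, ANO8, FOXE1 and BRF2 did not pass (edgeR BH-adjusted p from 0.0541 for FKBP5 to 0.194 for ANO8). Over 36 fits that left out single events or 1 fish place, KIF4 lost its call in 29, ANO8 and BRF2 in 25 each, HSP70B and P4HA2 in 11 each and HSP47 in 0. In heatwave 1 alone slopes moved both ways: HSP70B was at 0.04 and HMGB3 at -0.06, nearer to 0, and HSP47 at 0.87 and FKBP5 at 0.99, further from it.

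Heat shock proteins and co-chaperones rose as a group with temperature: 4 of 20 passed over all genes (HSP47, HSP90BA, HSP70B and HSP90BB, 0.10 per °C) and 8 adjusted over the list alone, with 0 falling. Limma's camera gave adjusted p = 2.5e-05 over the lists, and adjusted p = 0.0342 with an estimated correlation, which was the 1 list that passed both. Genes of the endoplasmic reticulum stress response had 0 of 16 past the threshold (1 adjusted over the list alone; HSP90B1 0.17, edgeR BH-adjusted p = 0.125; limma camera adjusted p = 0.014, adjusted p = 0.198 with an estimated correlation). Cell cycle genes lay below 0 in 12 of 15 cases (TPX2 -0.21, BUB1B -0.18, CDC20 -0.08; 0 past the threshold by edgeR, 2 adjusted over the list alone; limma camera adjusted p = 0.0105, adjusted p = 0.404 with an estimated correlation). Cytosolic ribosomal proteins did so in 24 of 32 (0 past by edgeR and 0 adjusted over the list alone; limma camera adjusted p = 0.0178, adjusted p = 0.571 with an estimated correlation). Erythrocyte markers lay above 0 in 9 of 10 (HBB4 0.18, HBA4 0.18; 0 past by edgeR and 0 adjusted over the list alone; limma camera adjusted p = 0.014, adjusted p = 0.404 with an estimated correlation). Without the 3 libraries with few contigs limma's camera gave adjusted p = 0.0488 for erythrocyte markers, and the same value for inflammatory mediators and oxidative phosphorylation, which had not passed.

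Other lists did not pass camera with temperature. In the glucocorticoid-responsive genes 1 of 6 rose (FKBP5; 2 adjusted over the list alone) and in collagens and matrix 1 of 28 (P4HA2; 3 rose and 1 fell adjusted over the list alone), with limma camera adjusted p = 0.0962 and 0.0865. The inflammatory mediators had 0 of 15 past the threshold (CCL21 0.06, SOCS3 0.11; limma camera adjusted p = 0.0718), the interferon response 0 of 18 (MX -0.19; 0.912), the circadian clock 0 of 13 (CRY1 0.12; 0.0865) and the hypoxia response 0 of 10 (EPAS1 0.06; 0.0535). No member passed in the lists of antioxidant genes, glycolysis, oxidative phosphorylation, proteasome, ion transport, antigen presentation, cholesterol synthesis, p53 and apoptosis, CCT, or markers of T cells, B cells, neutrophils and macrophages, endothelium, mucous cells, muscle and cartilage. Their limma camera adjusted p lay between 0.141 and 0.912. For ion transport, p53 and endothelial markers the camera direction and the sign of the list's median differed.

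Slopes were not shown to differ between streams. HSP47 had slopes of 0.49, 0.46, 0.47 and 0.71 log2 per °C in Big Poe, East Branch, Shavers and Standing Stone, and HS90A of 0.45, -0.14, 0.42 and 0.58. By edgeR, 0 genes passed the test of equal slopes, with 2071 at an unadjusted p under 0.05 and a smallest BH-adjusted p of 0.064. DESeq2 called 16, edgeR with each fish as the replicate 143, and limma with each fish 0. For the warm against the cool pair, edgeR called 0 slopes (1188 at an unadjusted p under 0.05, 4 by DESeq2, 4 by edgeR with each fish and 0 by limma with each fish).

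Between heatwave peak and recovery, HSP47 had the smallest p of all genes by edgeR, which does not make its difference the largest. It was 3.33-fold higher at the peak (log2 1.73 ± 0.20, edgeR BH-adjusted p = 7.33e-05) in 8 of 8 pairs of events, at 88.5 ± 46.1 CPM (SD, 8 events) against 25.7 ± 12.0 in recovery. It stood at 60.6 ± 22.7 CPM in the increasing phase and 44.6 ± 16.0 post-peak. The other feature that rose was SI_CH211-237L4.5 (0.58 ± 0.10, edgeR BH-adjusted p = 0.0307, higher in 8 of 8 pairs), chosen after its values were seen. Other chaperones did not pass: HS90A had a log2 difference of 0.95 ± 0.31 (edgeR BH-adjusted p = 0.487, higher in 6 of 8 pairs), HSP90BA 0.41 ± 0.11 (0.302, 8 of 8), HSP70 -0.04 and HSPA8 0.04. CIRBP was at 375 ± 93.8 CPM at the peak and 531 ± 98.9 in recovery (log2 -0.52 ± 0.14, edgeR BH-adjusted p = 0.31, lower in 7 of 8 pairs).

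The heat shock list was higher at the peak, with 1 of 20 past the threshold and 5 adjusted over the list alone (HSP90BB 0.32, HSP90B1 0.50; limma camera adjusted p = 5.36e-05, adjusted p = 0.15 with an estimated correlation). Cell cycle genes were lower in 13 of 15 (TPX2 -0.58, CDC20 -0.27; 0 past by edgeR and 0 adjusted over the list alone; limma camera adjusted p = 0.000912, adjusted p = 0.365 with an estimated correlation). Glucocorticoid-responsive genes were higher in 5 of 6 (FKBP5 1.27, SGK1 0.68), erythrocyte markers in 9 of 10 (HBA4 0.53) and endoplasmic reticulum genes in 11 of 16 (DNAJB9A 0.48), and ribosomal proteins lower in 26 of 32. For each of these 4 lists edgeR called 0 members, and 1 ribosomal member passed adjusted over the list alone. Limma's camera gave adjusted p = 0.0277 for each, and adjusted p = 0.232, 0.552, 0.305 and 0.552 with an estimated correlation in the order given. Without the 3 libraries with few contigs erythrocyte markers did not pass (limma camera adjusted p = 0.135). The remaining lists had 0 members past the threshold and limma camera adjusted p from 0.0551 to 0.914, with NR1D1 of the clock list at 0.51 and GPX3 of the antioxidant list at 0.37. For p53, muscle, interferon and glycolysis the camera direction differed in sign from the median or the mean.

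In that contrast edgeR called 2 genes, with 1748 at an unadjusted p under 0.05. The count was 1 to 5 without single events, 48 by DESeq2, 1 with events paired by a block for each stream and heatwave, and 0 with water temperature as a covariate, where HSP47 was at 1.17 (edgeR BH-adjusted p = 0.93). SI_CH211-237L4.5 lost its call in 15 of 36 fits that left out single events or 1 fish place, and HSP47 in 0.

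The peak was not told apart from the increasing and the post-peak phase. These are phases by label, and the East Branch peak of heatwave 1 was cooler than its increasing event. Peak against increasing gave 0 genes by edgeR (800 at an unadjusted p under 0.05, 3 by DESeq2, 0 by either test with each fish), and post-peak against peak gave 0 (1426, 3 by DESeq2, 8 by edgeR and 3 by limma with each fish). Over all 4 phases 1 gene differed, HSP47 (1163 at an unadjusted p under 0.05, edgeR; 11 by DESeq2). Without Big Poe or without Shavers 0 did.

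Heatwave 2 differed from heatwave 1 at matched phases in few genes. Heatwave 1 was sampled from 17 July to 2 August and heatwave 2 from 4 to 19 August, so heatwave and date cannot be told apart here. Phases were matched by name and not by temperature, and recovery was cooler in heatwave 2. IRAK3, a negative regulator of Toll-like receptor signalling, was higher in heatwave 2 by 0.34 ± 0.06 log2 (edgeR BH-adjusted p = 0.0249, higher in 15 of 16 pairs), at 44.5 ± 4.73 against 35.0 ± 4.18 CPM (SD, 16 events each). The other 2 genes past the threshold, named after their values were seen, were LOC101062919 (-0.49 ± 0.08, edgeR BH-adjusted p = 0.0188, lower in 16 of 16 pairs) and the unnamed contig_033606 (1.14 ± 0.20, 0.0329, higher in 15 of 16). Over 36 fits that left out single events or 1 fish place, contig_033606 lost its call in 20, IRAK3 in 6 and LOC101062919 in 3. HSP47 (-0.34 ± 0.14, edgeR BH-adjusted p = 0.455), HS90A (0.46), HSP70 (-0.03), HSPA8 (0.01) and CIRBP (0.03) did not pass.

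Collagens and matrix genes were lower in heatwave 2 in 21 of 28 (SPARC -0.33, lower in 14 of 16 pairs; COL1A2 -0.26; COL11A2 -0.76). Of these, 0 passed by edgeR and 3 were lower adjusted over the list alone (limma camera adjusted p = 0.0044, adjusted p = 0.388 with an estimated correlation). Without the 3 libraries with few contigs limma's camera gave adjusted p = 0.0151 for this list and for cell cycle genes, which were then higher in heatwave 2, and 0.0437 for B cell markers. Camera with an estimated correlation was not run without these libraries, and with all libraries it passed 0 lists for heatwave. B cell markers (CD37 -0.52, IGHM -0.39), ion transport (RHCG2 -0.46, the ammonia transporter), erythrocyte markers (HBA -0.48) and the remaining lists had 0 members past the threshold and limma camera adjusted p from 0.0558 to 0.894. Median, mean and camera differed in sign for the antioxidant, ribosomal, proteasome, interferon, clock and glucocorticoid lists.

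The count by edgeR was 3, with 2208 at an unadjusted p under 0.05, 148 by DESeq2 and 52 by limma with each fish. It was 0 with events paired by a block for each stream and phase (2204 at an unadjusted p under 0.05), where the 3 genes kept their direction. It was 54 without the East Branch recovery event of heatwave 1, 15 without the Shavers recovery of heatwave 2, 6 without the Standing Stone increasing event of heatwave 1 and 5 without the East Branch post-peak of heatwave 2. It was 0 without the East Branch post-peak of heatwave 1, and 1 without the increasing event of East Branch in heatwave 2 or of Shavers in either heatwave. Phase by heatwave gave 0 genes by edgeR (1583 at an unadjusted p under 0.05, 39 by DESeq2, 72 by edgeR and 0 by limma with each fish).

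Streams differed in 5559 of 24686 genes (edgeR, BH-adjusted). Big Poe and Shavers, the warm streams, differed from each other in 733 genes, and the cool streams East Branch and Standing Stone in 1249. East Branch differed from Shavers in 4535 and from Big Poe in 3894, and Standing Stone from Shavers in 1858 and from Big Poe in 1129.

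Between warm and cool streams, GP2, a zymogen-granule and mucosal glycoprotein that binds bacteria, showed the widest difference of the named genes. It was 53.7-fold higher in warm streams (log2 5.75 ± 0.50, edgeR BH-adjusted p = 2.78e-08), at 98.4 ± 58.4 CPM (SD, 8 events) in Big Poe and 191 ± 187 in Shavers against 0.498 ± 0.381 in East Branch and 11.1 ± 8.78 in Standing Stone. RNSL3 (4.87 ± 1.49), ANG1 (3.18 ± 0.69), LIN1 (2.10 ± 0.26), HA23 (1.65 ± 0.30), GBP4, an interferon-induced guanylate-binding protein (1.52 ± 0.22), HAAF (1.52 ± 0.25) and CSTF2, an mRNA 3′ cleavage factor (1.49 ± 0.14), were also higher in warm streams. Lower there were GIPC1 (-2.81 ± 0.40), SAHH2 (-1.97 ± 0.27), CDC34A, a ubiquitin-conjugating enzyme (-1.70 ± 0.50), G3P (-1.69 ± 0.11, edgeR BH-adjusted p = 6.16e-11), PTPRZ (-1.61 ± 0.24), PA2GX (-1.41 ± 0.15), IRK1 (-1.28 ± 0.13) and CRVP (-1.27 ± 0.25). G3P, the name of glyceraldehyde-3-phosphate dehydrogenase, stood at 58.5 ± 14.7 and 48.3 ± 16.1 CPM in Big Poe and Shavers and at 203 ± 40.2 and 143 ± 21.4 in East Branch and Standing Stone. HSP47 was higher in warm streams by 0.84 ± 0.14 and HSP90BA by 0.37 ± 0.07, while HS90A (0.47, edgeR BH-adjusted p = 0.121), HSP70 (-0.01), HSPA8 (-0.16) and CIRBP (-0.10) did not pass.

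**Figure D4:**
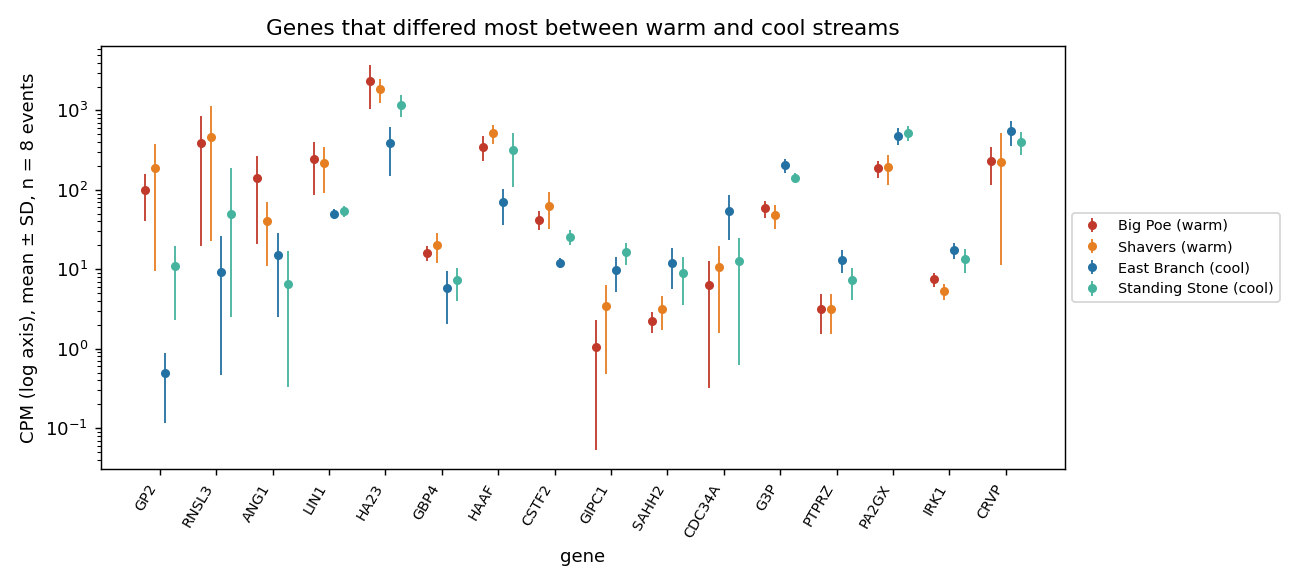
Mean CPM (log axis) of the 16 genes with the widest warm against cool differences under the rule, in each of the 4 streams, with SD over 8 events as bars (where the SD exceeds the mean the lower bar is shortened). GP2 was at 98.4 and 191 CPM in the warm streams and at 0.498 and 11.1 in the cool streams.

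Some genes of the cell cycle and immune lists were higher in the warm streams. Of 15 cell cycle genes 10 were higher and 0 lower (CCNA2 0.62, AURKB 0.72, BUB1 0.46; 10 adjusted over the list alone; limma camera adjusted p = 1.22e-05, adjusted p = 0.106 with an estimated correlation). Inflammatory mediators were higher in 7 of 15 (CCL2 0.86, CCL4 0.66, SOCS3 0.39; 7 adjusted over the list alone) and antigen presentation in 5 of 11 (TAP2A1 0.84, PSMB8B 0.56, TAP1 0.39; 7 adjusted over the list alone). Neutrophil and macrophage markers were higher in 6 of 11 (CSF3R 0.43, LYZ2 0.43, NCF1 0.49; 7 adjusted over the list alone) and the interferon response in 5 of 18 (IFI44 1.27, IRF1 0.81; 7 higher and 1 lower adjusted over the list alone). Limma's camera gave adjusted p = 0.00108, 0.00102, 0.00116 and 0.00297 for these 4 lists, and adjusted p = 0.0798 for each with an estimated correlation. T cell markers were higher in 3 of 6 (ZAP70 0.82; 4 higher and 1 lower adjusted over the list alone; limma camera adjusted p = 0.0332, adjusted p = 0.206 with an estimated correlation). B cell markers were higher in 3 of 6 (IGHM 1.11, CD22 0.38 and CD226; 3 adjusted over the list alone; limma camera adjusted p = 0.0615). CD226 is another gene that the symbol pattern took in.

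Some genes of protein folding and degradation were higher in the warm streams too. Endoplasmic reticulum genes were higher in 7 of 16 (PDIA4 0.49, HYOU1 0.55, PDIA3 0.46) and lower in 1 (CALRL -0.30), with 7 and 1 adjusted over the list alone (limma camera adjusted p = 0.00188, adjusted p = 0.0798 with an estimated correlation). Heat shock genes were higher in 7 of 20 and lower in 1, the small heat shock protein HSPB7 (-0.85), with 8 and 1 adjusted over the list alone (limma camera adjusted p = 0.0281, adjusted p = 0.229 with an estimated correlation). Proteasome genes were higher in 4 of 10 (4 adjusted over the list alone; limma camera adjusted p = 0.00399, adjusted p = 0.112 with an estimated correlation), of which PSMB8B and PSMB9-B are immunoproteasome subunits.

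Some matrix, erythrocyte and cholesterol genes were lower in the warm streams. Collagens and matrix genes were lower in 9 of 28 (POSTNA, periostin, -2.07; COL1A3 -0.63; COL5A1 -0.39) and higher in 1 (COL28A1 1.07), with 13 lower and 1 higher adjusted over the list alone (limma camera adjusted p = 0.00102, adjusted p = 0.121 with an estimated correlation). Erythrocyte markers were lower in 5 of 10, all 5 of them globins (HBB4 -1.09, HBA1 -1.12, HBA -0.63; 6 adjusted over the list alone; limma camera adjusted p = 0.00218, adjusted p = 0.206 with an estimated correlation). Cholesterol and fatty acid synthesis genes were lower in 4 of 10 (LDLR2 -0.92, the sterol-synthesis enzyme DHCR7 -0.48, SREBF1 -0.54; 6 adjusted over the list alone; limma camera adjusted p = 0.00458, adjusted p = 0.206 with an estimated correlation).

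Lists that did not pass camera held single genes that did by edgeR. AGR2 (0.84) and MUC2 (0.61) of the 6 mucous cell markers were higher in warm streams and MUC22 (-1.35) lower (limma camera adjusted p = 0.185). FOXI3B, a forkhead factor of ionocytes, was lower (-0.61) among the 7 ion transport genes (limma camera adjusted p = 0.168). Oxidative phosphorylation was lower in 5 of 38 (COX42 -0.55; limma camera adjusted p = 0.0507), glycolysis in 2 of 10 (LDHB -0.69) and higher in 1 (HK2 0.17; 0.16), and hypoxia lower in 2 of 10 (EPAS1 -0.31; 0.185). Higher were 4 of 20 antioxidant genes (GPX1 0.45, GSTP1 0.67; 0.307), 2 of 10 of p53 and apoptosis (CASP8 0.32; 0.322), 2 of 32 ribosomal proteins (RPL35A 0.72; 0.635) and CCT8 (0.64; 0.0799) of 2 CCT genes. Lower were CRY2 (-0.40) of 13 clock genes (0.105) and 2 of 17 muscle genes (CKM1 -0.43; 0.322). None of 6 glucocorticoid, 3 endothelial and 3 cartilage genes passed.

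In all, 2571 genes were higher and 2493 lower in the warm pair (edgeR, BH-adjusted; 8145 at an unadjusted p under 0.05). Each side held 2 streams, so the test compares these 4 streams and not stream types. Without the fish in the 3rd place of every event the count was 3056, and RNSL3 was at 3.77 and did not pass, against 8.55 without the 2nd place. It did not pass without the 4th place either, ANG1 ran from 2.53 (without the 3rd place) to 4.57 (without the 1st), and HK2 lost its call in 23 of 36 fits that left out single events or 1 fish place, CD22 in 2 and CDC34A and CKM1 in 1 each. Over the other alternatives LIN1 ran from 1.16 (mean log2 CPM) to 3.03 (contigs one by one). HA23 ran from 1.64 (without the 3 libraries with few contigs) to 2.84 (limma with each fish), and both kept their call.

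Between males and females edgeR called 0 genes. HSP47 differed by 0.00 ± 0.11 log2 between males and females, HS90A by -0.06, HSP70 by 0.09, HSPA8 by 0.13 and CIRBP by -0.07 (BH-adjusted p = 1 by edgeR for each). Of 24686 genes 1003 had an unadjusted p under 0.05, where chance gives 1234. DESeq2 called 0, and 2 contigs passed when contigs were tested one by one.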

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

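Of the tests in this part, that of sequencing depth was chosen only after its result was seen. Within each of the 23 events with 4 fish, 5 measures were compared between the fish, and a fish was singled out where its gap to the nearest of the other 3 exceeded Dixon's 95% critical value. Chance alone singles out about 1 in 20 groups, which would be 5.8 of those tested, and 17 were.

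Fish 44 of the Big Poe heatwave 1 recovery held 11.45 M reads against 8.37 to 8.85 M in the other 3. Fish 27 of the Shavers heatwave 1 peak had 42304 contigs detected against 43651 to 43842.

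The share of reads in 45S rRNA features stood apart in 6 of 23 events. It was 8.42% in fish 39 of the Big Poe heatwave 1 post-peak (others 3.31% to 3.7%), 6.3% in fish 57 of the Big Poe heatwave 2 peak (2.59% to 3.06%) and 6.2% in fish 63 of the Big Poe heatwave 2 post-peak (2.65% to 2.99%). It was 6.52% in fish 44 of the Shavers heatwave 1 post-peak (2.27% to 2.46%), 1.29% in fish 44 of the East Branch heatwave 2 recovery (2.64% to 2.73%) and 0.57% in fish 51 of the Standing Stone heatwave 2 post-peak (2.49% to 2.63%).

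HSP47 stood apart in 4 of 23 events, each time low. It was at 5.82 log2 CPM in fish 53 of the Big Poe heatwave 2 increasing phase (others 6.21 to 6.23), 2.35 in fish 75 of the Big Poe heatwave 2 recovery (4.47 to 4.84), 5.48 in fish 61 of the Shavers heatwave 2 peak (6.76 to 6.88) and 5.06 in fish 47 of the Standing Stone heatwave 2 peak (5.83 to 5.9). Fish 75 and 61 are among the 3 libraries with few contigs.

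The mean of the erythrocyte markers was 6.21 log2 CPM in fish 25 of the East Branch heatwave 2 increasing phase (others 5.48 to 5.58), 2.57 in fish 44 of the East Branch heatwave 2 recovery (5.25 to 5.66) and 4.45 in fish 56 of the Shavers heatwave 2 increasing phase (5.42 to 5.55).

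The 3 libraries with the fewest contigs were fish 44 of the East Branch heatwave 2 recovery (13621 against 41909 to 45160), fish 75 of the Big Poe heatwave 2 recovery (31018 against 42745 to 44038) and fish 61 of the Shavers heatwave 2 peak (29147). Sequencing depth as their common cause is argued against by fish 75, the deepest library of all with 14.71 M reads, although fish 44 held 1.06 M. A few genes taking most of the reads as their common cause are argued against by fish 75 and 61, whose 20 most abundant genes took 17.34% and 17.73% against a median of 19.8% in the other libraries, but fish 44 had 22.78%, above their 75th percentile of 20.4% and below their highest value of 24.4%, so for that library it stays open. A loss of library complexity before sequencing, RNA quality and a different make-up of the tissue sample stay open and were not tested. No biological explanation was tested: the 3 fish come from 3 streams, all from heatwave 2, and 2 of them from its recovery phase.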

How the results depend on the processing

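Chosen only after the data were seen were the fits without the 3 libraries with few contigs, without 45S features, without the heatwave 2 recovery events and within 1 heatwave, the fits with a block that pairs events, and the extended gene lists. Counts below are genes at a BH-adjusted p under 0.05. As reported, edgeR gave 109 for temperature, 0 for stream by temperature, 0 for warm against cool slopes, 1 over the phases, 0 for peak against increasing, 0 for post-peak against peak, 2 for peak against recovery, 3 for heatwave, 0 for phase by heatwave, 5559 for streams, 5064 for warm against cool streams and 0 for sex. The unadjusted counts behind the 0s are 2071, 1188, 800, 1426, 1583 and 1003 in that order. Counts of single settings not given below lay within 1.5 times of these. Of the 103 gene results past the threshold, 4480 of 4934 values under the alternatives kept direction and call, 454 kept the direction and lost the call, and 0 reversed. Most of these values come from fits that left out 1 event or 1 fish place and share most of their data with the main fit. The genes were chosen for passing in that fit, so few reversals had to be looked for. Of the 55 gene results short of it, 2510 of 2641 values stayed so, 53 passed and 78 reversed. The cause of the changes below was not tested. By construction, edgeR with each fish as a replicate ignores what the fish of an event share.

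With each fish as the replicate edgeR gave 216 genes for temperature, 143 for stream by temperature, 4 for warm against cool slopes, 48 over the phases, 8 for post-peak against peak, 54 for peak against recovery, 103 for heatwave and 72 for phase by heatwave. Limma with each fish and a correlation within events gave 232 for temperature (152 higher and 80 lower, against 60 and 49 as reported), 21 over the phases, 3 for post-peak against peak, 35 for peak against recovery and 52 for heatwave. DESeq2 gave 342 for temperature, 16 for stream by temperature, 4 for warm against cool slopes, 11 over the phases, 3 for peak against increasing, 3 for post-peak against peak, 48 for peak against recovery, 148 for heatwave and 39 for phase by heatwave. With the mean log2 CPM of the fish, limma gave 49 for temperature (37 higher and 12 lower), 1 for peak against recovery and 0 for heatwave.

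Contigs tested one by one gave 4 for peak against recovery, 5 for heatwave, 8651 for streams, 7709 for warm against cool streams and 2 for sex. RLE factors gave 1 for stream by temperature, and no filter gave 1 for it and 2 over the phases. With the share of females as a covariate temperature had 48. Sex was not balanced over events: all 4 fish were female in the heatwave 2 recoveries of Big Poe and Standing Stone, the coldest events of these streams. All fish were female also in some warmer events, such as the Shavers heatwave 1 increasing phase. With water temperature as a covariate there were 0 over the phases, 0 for peak against recovery and 48 for heatwave.

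Without Big Poe edgeR gave 0 for temperature, 0 over the phases, 1 for peak against recovery and 0 for heatwave. Without East Branch the counts were 22 for temperature, 1 for peak against recovery and 1 for heatwave. Without Shavers they were 29 for temperature, 0 over the phases, 1 for peak against recovery and 0 for heatwave, and without Standing Stone 0 for heatwave. Temperature had 0 genes without the heatwave 2 recovery events, 0 in heatwave 1 alone and 2 in heatwave 2 alone. Without the 3 libraries with few contigs it had 42, and heatwave 7.

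Leaving out single events, or the fish of 1 place in every event, moved the temperature count from 3 (without the Big Poe heatwave 2 recovery) to 183 (without the 4th place). The other places gave 34, 54 and 4. Without the Big Poe peaks of heatwaves 1 and 2 it was 51 and 71, and without the Shavers heatwave 2 peak 174. Stream by temperature ran from 0 to 4 (without the Shavers heatwave 2 recovery), with 1 without the Big Poe heatwave 1 peak or the Shavers heatwave 1 increasing event. Warm against cool slopes ran from 0 to 1 (without the 2nd place) and phase by heatwave from 0 to 1 (without the 2nd place or the Big Poe heatwave 2 recovery). Peak against recovery ran from 1 to 5 (without the Shavers heatwave 1 recovery). It was 1 without the 2nd, 3rd or 4th place, either peak or recovery event of Big Poe, either recovery of East Branch, either peak of Shavers, its heatwave 2 recovery, or the heatwave 1 peak or recovery of Standing Stone. Heatwave ran from 0 (without the East Branch heatwave 1 post-peak) to 54 (without the East Branch heatwave 1 recovery). It was 0 also without the 1st or 2nd place, 14 without the 3rd, 15 without the Shavers heatwave 2 recovery, 6 without the Standing Stone heatwave 1 increasing event, 5 without the East Branch heatwave 2 post-peak, and 1 without the increasing event of East Branch in heatwave 2 or of Shavers in either. Streams ran from 3621 (without the 3rd place) to 5558, and warm against cool streams from 3056 (without the 3rd place) to 5108. Of the libraries with few contigs, East Branch fish 44 was in the 1st place, Big Poe fish 75 in the 3rd and Shavers fish 61 in the 4th.

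Camera had passed 5 gene lists for temperature, 6 for peak against recovery, 1 for heatwave and 12 for warm against cool streams. With an estimated correlation it passed 1, 0, 0 and 0. Fry passed 2 for temperature, 1 for peak against recovery, 0 for heatwave and 21 for warm against cool streams. Of the extended lists camera passed 9 for temperature, 10 for peak against recovery and 9 for heatwave, and without the 3 libraries with few contigs 3 of the fixed lists for heatwave.

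Of the 103 gene results past the threshold that were followed one by one under the alternatives, 0 changed direction. Among all 109 genes past it with temperature, 108 kept their sign in heatwave 1 alone. They were picked in a fit that holds these events, so this is no separate support. Not followed one by one were HSPB7, CALRL, COL28A1, NHE3B, FXI1E, CAHZ, VPP3, B3AT, K1C13, K2C8 and CIRBB for warm against cool streams. The same holds for DNJA1, RS20 and RLA0 with temperature, which were refitted only as part of the 109. Among genes short of it, signs turned as follows, in log2. With each fish, HSP70 was at 0.01 for heatwave in edgeR, and in limma at 0.03 for peak against recovery and 0.03 for warm against cool streams, with HSPA8 at -0.04 for heatwave. SERPH had a temperature slope of -0.01 by contigs. HS90A was at 0.15 for sex with stream, heatwave and phase as covariates. With the mean log2 CPM HSP70 was at 0.04 for peak against recovery and 0.04 for warm against cool streams, and HSPA8 at -0.07 for heatwave. With temperature as a covariate peak against recovery was -0.31 for FKBP5, -0.25 for HS90A, 0.17 for HSP70 and -0.10 for HSPA8. Without Big Poe HSP70 had a slope of 0.04 and HSPA8 a peak difference of -0.04. Without East Branch HSP70 had one of 0.12. Without Shavers the heatwave differences were -0.05 for CIRBP, 0.01 for HSP70 and -0.05 for HSPA8, and without Standing Stone -0.02 for CIRBP. With events paired by stream and phase HSPA8 was at 0.00 for heatwave, on the other side of 0. The HSP70 slope was 0.03 without the heatwave 2 recovery events and 0.01 in heatwave 1 alone. Over single events or places left out, HSP70 ran from -0.06 to 0.05 for temperature, -0.15 to 0.09 for peak against recovery, -0.08 to 0.02 for heatwave, -0.07 to 0.04 for warm against cool streams and -0.01 to 0.23 for sex. HSPA8 ran from -0.02 to 0.09 for peak against recovery, -0.03 to 0.06 for heatwave and -0.02 to 0.31 for sex. CIRBP ran from -0.01 to 0.07 for heatwave, HS90A from -0.19 to 0.07 and HSP47 from -0.12 to 0.12 for sex.

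Fish numbers that recur between streams and events name different fish and pair nothing. Events were paired instead by a replicate block for each stream and heatwave, which gave 1 gene over the phases and 1 for peak against recovery, and for each stream and phase, which gave 0 for heatwave by edgeR (2204 at an unadjusted p under 0.05, 148 by DESeq2 without the block). What could be seen was gauged only in simulated data without stream differences or shared days. There, 79% of slopes of 0.2 log2 per °C and 52% of peak differences of 0.5 were recovered, and smaller ones were not simulated.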

Other observations

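The genes of the first 2 paragraphs were chosen after their values were seen, on gene lists extended to the naming of the files, also after the data were seen. Ion transport genes went both ways between warm and cool streams and did not pass as a list. Lower in the warm streams were NHE3B, a sodium-proton exchanger, by log2 -0.92 (edgeR BH-adjusted p = 6.1e-09), FXI1E and FOXI3B, forkhead factors of ionocytes, by -0.80 and -0.61, and CAHZ, a carbonic anhydrase, by -0.26, while VPP3, a subunit of the proton pump, was higher by 0.39. Of the 21 ion transport genes of that list 5 were lower and 2 higher (limma camera adjusted p = 0.0794). B3AT, the anion exchanger of erythrocytes, was lower by -0.87 (edgeR BH-adjusted p = 1.49e-09). Keratins K1C13 (-0.72) and K2C8 (-0.56) were lower, and K1C1 (0.12) and K1C18 (0.00) did not pass. Of the 32 proteasome genes of the extended list 13 were higher in warm streams and 0 lower (limma camera adjusted p = 1.82e-06, adjusted p = 0.195 with an estimated correlation).

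A second cold-inducible RNA-binding protein, CIRBB, had a temperature slope of -0.29 ± 0.07 log2 per °C (edgeR BH-adjusted p = 0.06, negative in 4 of 4 streams), a log2 difference of -1.15 ± 0.23 between peak and recovery (0.109, lower in 8 of 8 pairs) and of -0.75 ± 0.16 between warm and cool streams (0.00136). SERPH, the other name for serpin H1, did not follow HSP47: its slope was 0.03 ± 0.03 and its peak difference 0.11 ± 0.10 (edgeR BH-adjusted p = 0.876). In the extended heat shock list 6 of 33 rose with temperature, among them HS90A and DNJA1 (0.13 per °C; limma camera adjusted p = 1.22e-07, adjusted p = 0.0441 with an estimated correlation). Of 104 ribosomal proteins 2 fell, RS20 (-0.13) and RLA0 (-0.12), with limma camera adjusted p = 9.04e-09 and adjusted p = 0.434 with an estimated correlation.

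Of the tests that follow, those of day temperature on the stream differences, of 1 event, the date and the 3 libraries on the temperature slopes, of both heatwaves and of HSP47 at equal temperature were chosen only after the result was seen.

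Warm and cool streams differed in 5064 genes, and the water temperature on the day of sampling is argued against as the common cause: 47.2% of these genes (2388) had a within-stream slope of the same sign, against 46.9% of all genes. It stays open for part of the 37 genes that passed both tests (22.4 by chance), of which 26 had the same sign. At equal water temperature, in the fit of stream and temperature, 2014 genes differed between warm and cool streams. That count relies on a linear slope and a partly shared temperature range, so its distance from 5064 decides nothing. Sequence differences between trout of the streams could move reads between contigs of one name and cannot be told apart from expression here: of the 1632 genes with at least 2 tested contigs 7.3% (119) had contigs past the threshold in both directions, between the bounds set for either outcome, and genes on 1 contig cannot show it. Differences in the cells of the sample also stay open, since several erythrocyte markers were lower and several immune markers higher in the warm streams. Long-term temperature, genetic background and other properties of the streams are confounded with the 4 streams, and these biological explanations were not tested.

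The 109 slopes with temperature are weighed against 3 sources. The Big Poe recovery event of heatwave 2 alone is argued against, since without it the slopes kept a median of 0.91 of their size (5th to 95th percentile 0.54 to 1.19) and 109 of 109 their sign, though 2 still passed. A linear trend with the date is argued against by a median ratio of 1.02 with the day as a covariate (0.76 to 1.26, 53 still past). The 3 libraries with few contigs as a joint source are argued against by 0.85 without them (0.53 to 1.08, 35 still past). None of these libraries was left out alone, so opposite effects of single libraries are not excluded. The heatwave 2 recovery was the coldest or joint coldest event of each stream, so these fits do not exclude an effect of those dates. Without the 4 recovery events of heatwave 2 the median ratio was 0.97 (0.42 to 1.4) and 0 still passed. It was 0.88 without Big Poe (0.43 to 1.23, 0 past) and 1.02 in heatwave 1 alone (0.15 to 1.96, 0 past). Without the fish in the 3rd place of every event, which keeps all 32 events, 4 still passed at a median ratio of 0.88. That place held fish 75 of the Big Poe heatwave 2 recovery, a library with few contigs. Why calls ended was not tested in any of these fits. The 109 genes were picked in a fit that holds the same events, so kept signs and sizes are partly built in. A response to temperature stays a hypothesis for the group.

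A first hypothesis was that the same genes follow temperature in both heatwaves. Of the 100 genes with the smallest p in heatwave 1 alone, 67% had the same sign in heatwave 2, and 20 of 100 assignments of the heatwave 2 temperatures within streams, the real one included, gave as much (permutation p = 0.2, one-sided; median of the others 50%, highest 76%). The hypothesis was not supported at this sample size.

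A further hypothesis was that HSP47 follows absolute water temperature alike in every stream, so that warm and cool streams would not differ at equal temperature. Its slope times the mean difference of 3.49 °C would give 1.78 log2, and the streams differed by 0.84 ± 0.14. At equal temperature HSP47 was lower in the warm streams by -0.96 log2 (SE 0.28, edgeR BH-adjusted p = 0.0307). That argues against it only if a linear slope holds across both pairs of streams and is not overestimated. For a gene that rises, an overestimated slope pushes this difference down. FKBP5, HSP70B and HSP90BA were named by their slope or p in these same events. FKBP5 was at -1.76 ± 0.52 (0.0341), HSP70B at -0.63 ± 0.24 (0.0928), HSP90BA at -0.12 ± 0.12 (0.6), HS90A at -0.94 ± 0.34 (0.0859) and CIRBP at 0.47 ± 0.19 (0.123). Of the 4 heat shock genes that rose with temperature, 1 had such an opposite difference past the threshold, HSP47 itself, so for the group the hypothesis stays open. A response set relative to a stream's usual temperature may account for HSP47, but warm and cool streams share only part of their temperature range, so the difference relies on a linear slope. Of the warm events only the heatwave 2 recoveries of Big Poe (14.0 °C) and Shavers (15.7 °C) lay within the range of the cool streams (12.9 to 16.1 °C). The Big Poe event held fish 75, a library with few contigs and HSP47 at 2.35 log2 CPM (others 4.47 to 4.84). The fit at equal temperature was not run without that library.

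Other assignments of the same events to the groups tested whether chance gives as many genes. For the temperature slope 3 of 100 assignments within streams, the real one included, gave at least 109 genes, a share under 0.05, with 393 in the highest other. For peak against recovery 4 of 100 gave at least 2 genes (highest other 81), for heatwave 1 of 100 gave at least 3 (highest other 1) and for any stream difference 1 of 100 gave at least 5559 (highest other 58). Chance is excluded at the 0.05 level for these counts only where events are exchangeable within a stream or phase. The counts are those of the fits without a block that pairs events. With the block heatwave gave 0 genes and peak against recovery 1, and those counts were not tested in this way. Big Poe and Standing Stone were sampled on the same days, and East Branch and Shavers on the same days but for the first event, and the assignments for temperature, phase and heatwave do not keep these shared days, so an effect of the day that streams share was not excluded. Chance was not excluded for the 1 gene over all phases, which 7 of 100 gave (highest other 446). Counts of 0 are reached by any assignment, so the test decides nothing for them: 100 of 100 did for the stream by temperature interaction (highest other 6), warm against cool slopes (14), peak against increasing (52), post-peak against peak (1817) and phase by heatwave (2). The splits with 393, 1817, 446 and 81 genes may point to a structure of the samples, but what these splits share was not examined. The 3 pairings of the 4 streams are too few for a share under 0.05: the real one gave 5064 genes and the highest other 1029, with 1 of 3 as large. For sex the count of 0 is likewise reached by any split, 8 of the 8 run (highest other 0).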
